A study of Homo sapiens with 6 samples.

How the data were processed

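Gene expression was measured in 6 samples of HEK293 cells, 3 transfected with a control siRNA and 3 with a BAHD1 siRNA for 72 h, with one biotin-labelled target hybridised to one array per sample. Per the labels' protocols, total RNA was purified with a kit and labelled from oligo(dT) primers by one cycle of in vitro transcription. The submitters' processing notes name GCOS and GCRMA, without versions or roles. The deposited table holds one intensity per probe set and array on a linear scale with 1 decimal, from 0 upward. The mean of each column without its highest and lowest 2% was 100, which is how GCOS scales arrays, so the table was taken as scaled GCOS-type signal. No GCRMA step can be seen in it, and which software wrote it is not given in the sources used here. Detection calls were not used here, so the lowest signals have no stated background. Signals of this kind are noisy when dim, and arrays scaled by one factor can still differ in a signal-dependent way.

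Samples were grouped by their titles, which also number the replicates. Control probe sets, 62 of 54675, were left out of the tests. The design, written before the data were examined, assumed GCRMA values on the log2 scale. As the table was linear, its stated substitute log2(value + 1) was used, which shrinks fold changes of dim probe sets somewhat. Those named below for the largest changes are noisy and can still be overstated. A probe set was kept when its value was above the median of all non-control values, a signal of 17.9, in at least 3 of the 6 arrays. This kept 27458 probe sets, of which 23546 are annotated with 1 gene, 1110 with several and 2802 with none in the platform annotation given. Symbols were checked through their gene identifiers against the RefSeq gene table of assembly GRCh38.p14, and 0 needed an update. Genomic positions are not printed, because no build is named for the array values. Genes were named only from probe sets with 1 gene, except for IGF2, whose probe sets all carry the INS-IGF2 readthrough gene as well.

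BAHD1 siRNA was compared with control siRNA in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, one variance prior, no covariates, all 6 arrays), with Benjamini-Hochberg adjustment and a threshold of 0.05. Two-sided exact permutation tests were added for single values. An alternative set beforehand let the prior follow the mean signal (eBayes with trend and robust), and because the first fit called no probe set, it is reported beside it throughout as the intensity-trend fit; this choice of emphasis was made after seeing the counts. For gene lists, each gene was represented by its brightest kept probe set over all 6 arrays, giving 12529 genes. The 21 lists, with 675 distinct genes of which 473 were measured and 68 have no probe set annotated to them alone, were fixed before the data were examined. They were tested with camera (preset correlation 0.01, and an estimated correlation as an alternative) and with fry. Camera compares a list with the other genes, whereas fry does not.

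Named genes followed a rule fixed beforehand: BAHD1 and IGF2, the 12 largest rises and 12 largest falls among called probe sets of 1 gene with no overlap between groups, the 5 smallest p-values per direction where fewer than 5 passed, and the 4 smallest p-values in each list. As the fit with one prior called none, the rule for largest rises and falls was applied to the intensity-trend fit after seeing this. Other list members that passed in that fit, or over the list alone, are named in part as well, chosen after their values were seen.

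The scripts were tested on simulated arrays made from the real means of the 27458 probe sets with 200 changed. The spreads were those estimated by the intensity-trend fit, and the noise was independent between probe sets. The comparison of the fits therefore favours the intensity-trend fit, and a shift that goes with the group was not simulated. For a log2 change of 0.5, 1 and 2, the fit with one prior recovered 1.12%, 49.1% and 87.4% of changed probe sets and the intensity-trend fit 40.1%, 74.8% and 89.8%. With no change simulated, they called 0.1 and 1.1 probe sets on average over 20 simulations. With 200 changed, 5.2 of the 96.55 calls of the fit with one prior and 12.95 of the 149.2 calls of the intensity-trend fit were false on average, a share above the 5% aimed at in both and larger in the latter.

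The number of arrays limits the precision. No pair of arrays held identical values in more than 0.291% of probe sets, so no array was taken as a copy. The labels give no processing batch. Alternatives were a replicate block, no filter and a stricter filter (75th percentile), quantile normalisation, centred array medians, array weights, log2(value + 16), other thresholds, other ways to represent a gene, and leaving out each array in turn. No siRNA sequences were used here, so effects of the siRNA on other transcripts were not examined.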

Results

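BAHD1 is a chromatin protein with a bromo-adjacent homology domain that is known to take part in heterochromatin formation and gene silencing. To ask which transcripts change when it is depleted, HEK293 cells, a line derived from human embryonic kidney, were transfected with a BAHD1 siRNA or a control siRNA, and total RNA was taken 72 h later. One array was hybridised per sample, giving 3 biological replicates per group. Each array measured 54675 probe sets on one scale, and the median signal per array ran from 15.9 to 19.5. Pairs of arrays from the same group correlated at r = 0.974 to 0.978 on the log2 scale, against 0.966 to 0.972 for pairs from different groups. The first principal component held 30.8% of the variance and placed the 3 control arrays on one side of 0 and the 3 BAHD1 siRNA arrays on the other.

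The BAHD1 transcript itself was measured by 1 probe set, and its level in the siRNA samples was 76.0% of the control level, from group means on the log2(signal + 1) scale. The mean log2 signal was 5.80 ± 0.21 (SD, n = 3) in control cells and 5.40 ± 0.17 (SD, n = 3) in BAHD1 siRNA cells. The log2 fold change was -0.40 with an SE of 0.15, which did not pass the test (limma, adjusted p = 0.251); its unadjusted p was under 0.05 in the fit with one prior and above it in the intensity-trend fit. The signals were 62.9, 55.7 and 46.7 in the control arrays and 36.6, 46.8 and 41.2 in the BAHD1 siRNA arrays, so that the highest knockdown value lay at the level of the lowest control value. The exact two-sided permutation p was 0.2, and 3 samples against 3 cannot give an exact p below 0.1. Where the siRNA binds relative to this probe set is not given in the sources used here.

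IGF2, a growth factor gene that BAHD1 is known to repress, was read by 3 probe sets that the annotation assigns jointly to IGF2 and the INS-IGF2 readthrough gene, so the signal cannot be given to one of them. Only 1 of the 3 was bright enough to be tested. Its log2 signal was 4.35 ± 0.64 (SD, n = 3) in control cells and 5.30 ± 0.25 (SD, n = 3) in BAHD1 siRNA cells, a difference of 0.95 with an SE of 0.33. All 3 knockdown values lay above all 3 control values (exact two-sided permutation p = 0.1, the smallest possible). The difference did not pass the test across probe sets (limma, adjusted p = 0.231, and 0.115 in the intensity-trend fit; both were under 0.05 unadjusted). Without control replicate 1 it was 0.59.

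**Figure D1:**
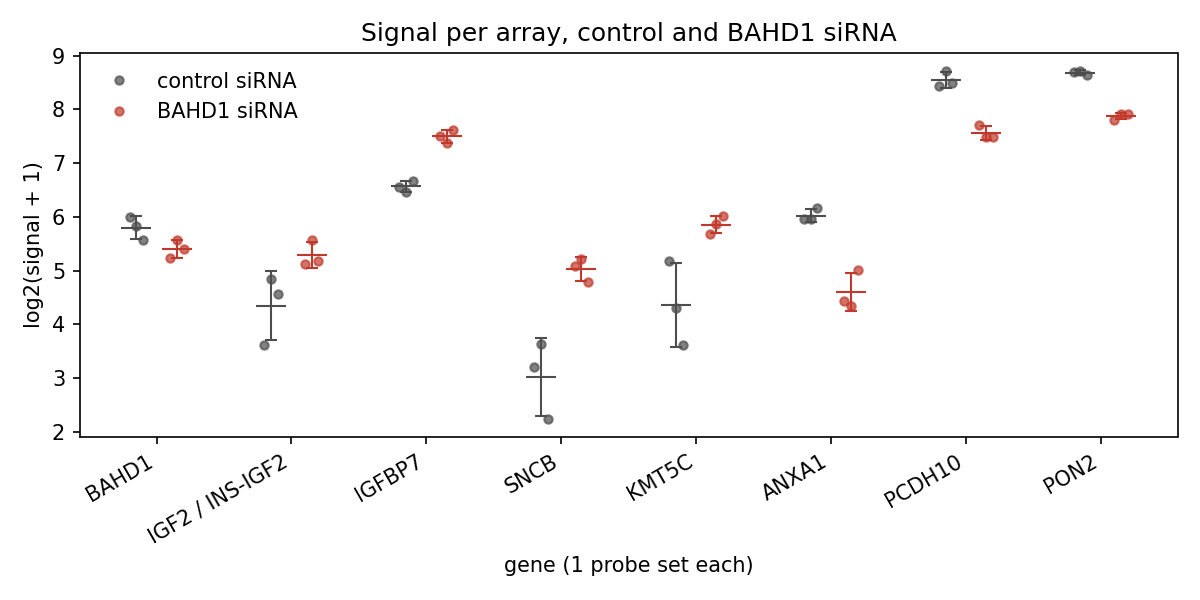
Log2(signal + 1) of 8 genes on each of the 6 arrays, with horizontal bars for the group mean and whiskers for 1 SD (n = 3 per group). BAHD1 signals of the groups met at 46.7 and 46.8 on the linear scale, whereas the groups of the other 7 probe sets did not overlap. For SNCB, KMT5C, ANXA1 and PCDH10 the naming rule required this, and IGFBP7 and PON2 were named for a small p-value.

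Many probe sets differed by small amounts. Of 27458 probe sets kept for testing, 4843 had an unadjusted p under 0.05 (2686 higher and 2157 lower in BAHD1 siRNA cells), where chance alone would give 1373. In 25.6% of probe sets the groups did not overlap, against 10% by chance. The limma fit fixed before the data were examined, which uses one variance prior for all probe sets, called none of them after Benjamini-Hochberg adjustment (smallest adjusted p = 0.112). A second fit set beforehand, in which limma's prior variance follows the mean signal (the intensity-trend fit), called 1221 probe sets at an adjusted p under 0.05, of which 596 rose and 625 fell. The median size of these changes was 0.45 on the log2 scale, and 34 rises and 8 falls reached 2-fold. With the array medians centred the split was 458 rises and 746 falls. Below, rose and fell are used of genes past the threshold in the intensity-trend fit, none of which passed over all probe sets in the fit with one prior.

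The count of calls in the intensity-trend fit rested on several arrays. It was 295 without control replicate 1, 279 without control replicate 2, 186 without BAHD1 siRNA replicate 2 and 177 without BAHD1 siRNA replicate 3, and 1174 and 1132 without control replicate 3 and BAHD1 siRNA replicate 1. It was 398 when no filter on dim probe sets was applied. Of the 177 calls made without BAHD1 siRNA replicate 3, 173 were among the 1221. The larger sets shared less: 820 of the 1174 calls without control replicate 3 and 831 of the 1132 without BAHD1 siRNA replicate 1. Similar counts thus do not mean the same probe sets.

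**Figure D2:**
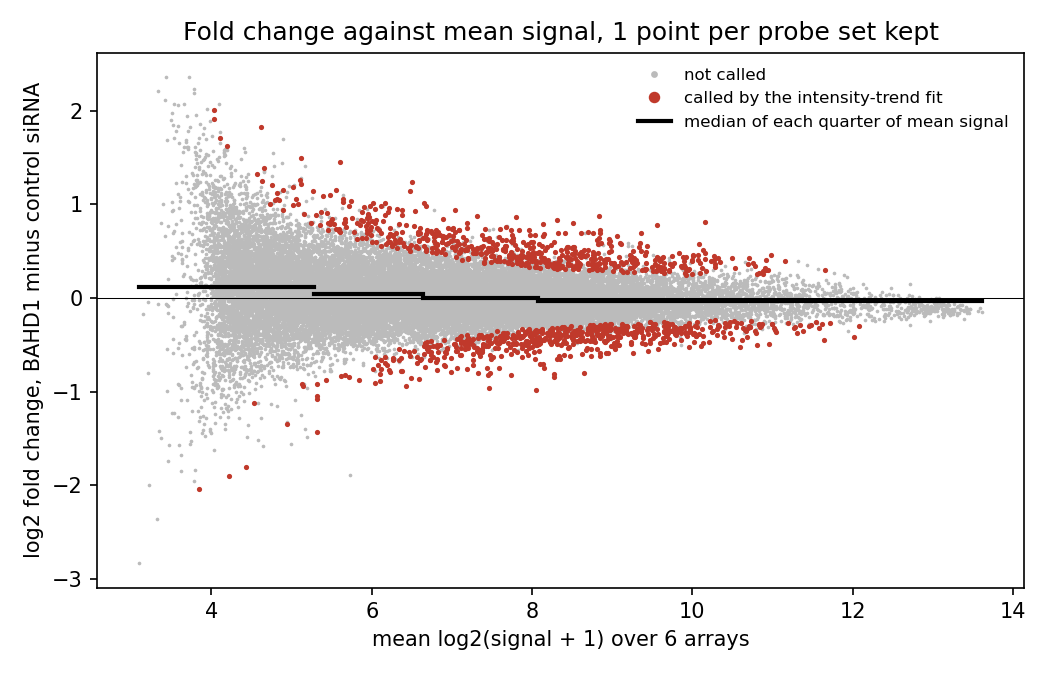
Log2 fold change of BAHD1 siRNA over control siRNA (vertical) against the mean log2(signal + 1) over the 6 arrays (horizontal), 1 point per probe set kept, with calls of the intensity-trend fit in red and black lines at the median of each quartile of mean signal. The median log2 fold change ran from 0.11 in the dimmest quartile to -0.04 in the brightest, which held 258 of the 596 rises and 384 of the 625 falls.

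The largest rises in the intensity-trend fit were in genes that were dim in control cells. SNCB, which encodes the neuronal protein beta-synuclein, rose by 2.01 ± 0.48 (log2 fold change ± SE, 3 arrays per group), and IDO1, an enzyme of tryptophan breakdown, by 1.91 ± 0.44. CTSS, the lysosomal protease cathepsin S, rose by 1.62 ± 0.41, and KMT5C, a histone H4 methyltransferase, by 1.49 ± 0.33. The beta-tubulin gene TUBB4A rose by 1.39 ± 0.36, the transcription factor gene HLF by 1.32 ± 0.30 and the lipase maturation factor gene LMF1 by 1.22 ± 0.31. BPIFA3, ELFN2, DUSP19, MICAL3 and ZSCAN32 completed the 12 largest, at log2 fold changes of 1.71, 1.26, 1.25, 1.20 and 1.18. Adjusted p for these 12 ran from 0.0165 to 0.0462. Their mean control signals were 7.8 to 23.6, and 8 of the 12 were under the median signal of 17.9 for the whole data set. A probe set could be kept through the 3 BAHD1 siRNA arrays alone. SNCB, IDO1, BPIFA3, CTSS and HLF were kept in this way, as all their control log2 signals lay below the filter level of 4.24. Those of SNCB were 3.20, 3.64 and 2.23. Among rises, the filter and the ranking by log2 fold change thus favour genes that are dim in control cells. Among falls they favour genes that are dim in BAHD1 siRNA cells. On the log2(signal + 16) scale, which shrinks differences of dim probe sets, the 12 lay between 0.77 and 1.02, with SNCB at 1.02, IDO1 at 0.98, BPIFA3 at 0.90 and CTSS at 0.88.

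The largest falls were in GFOD3P (-1.90 ± 0.41) and in ANXA1 (-1.43 ± 0.22), which encodes the phospholipid-binding protein annexin A1. KCNC4, a voltage-gated potassium channel gene, changed by -1.13 ± 0.30 and B4GALT6, a glycosphingolipid synthesis gene, by -1.08 ± 0.23. GFOD3P and KCNC4 were kept through the control arrays alone, as all their BAHD1 siRNA values lay below the filter level. PCDH10, which encodes a protocadherin adhesion molecule, changed by -0.98 ± 0.10 from a control signal of 373 to 189. The cell polarity gene LLGL1 changed by -0.94 ± 0.23, the mitochondrial arginyl-tRNA synthetase gene RARS2 by -0.91 ± 0.21 and DOT1L, a histone H3 methyltransferase gene, by -0.91 ± 0.17. CCDC157, MPPE1, UBL3 and GNL1 also fell, by 1.35, 1.05, 0.96 and 0.89 on the log2 scale. Adjusted p for these 12 ran from 0.00159 to 0.0488, and on the log2(signal + 16) scale they lay between -1.03 and -0.65, with GFOD3P at -1.03, CCDC157 at -0.89 and KCNC4 at -0.68. Of the 24 genes named in both directions, 17 had more than 1 probe set kept, and in 2 of those 17 (LMF1 and B4GALT6) a further probe set was called. For KCNC4, CCDC157, DUSP19, MICAL3, LMF1, LLGL1 and GNL1 another probe set of the gene had a fold change of the opposite sign.

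In the fit with one prior, the smallest p-values among higher probe sets belonged to VIT, NHSL1, FLVCR2, GNA11 and IGFBP7, with log2 fold changes of 1.31, 1.71, 1.07, 0.86 and 0.94. Among lower ones they belonged to UBXN10, KCNC4, PON2, TNKS2 and JAM3, with -2.36, -1.13, -0.81, -0.80 and -0.71. All 10 had an adjusted p of 0.112 there. VIT, NHSL1 and FLVCR2 were kept through the BAHD1 siRNA arrays alone, and UBXN10 and KCNC4 through the control arrays alone. On the log2(signal + 16) scale UBXN10, with a knockdown signal of 3.5, was at -0.95, KCNC4 at -0.68, and VIT, NHSL1 and FLVCR2 at 0.70, 0.74 and 0.58. Of the 10, GNA11 (a G protein alpha subunit), IGFBP7 (an insulin-like growth factor binding protein), KCNC4, PON2 (a paraoxonase), TNKS2 (a tankyrase) and JAM3 (a junctional adhesion molecule) passed in the intensity-trend fit. Of the 6 probe sets kept for GNA11 1 was called, and the other 5 ran from -0.21 to 0.25.

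Control probe sets differed between the groups in part. The 24 probe sets for bacterial poly-A RNAs, which are added to a sample before labelling, were all higher in BAHD1 siRNA arrays, at a median of 1.49 times the control level. Their mean log2 signal was 8.63 ± 0.12 (SD, n = 3) in control arrays and 9.21 ± 0.17 (SD, n = 3) in BAHD1 siRNA arrays, with no overlap between groups for any of the 24 (exact two-sided permutation p = 0.1, the smallest possible). The 18 hybridisation controls, added after labelling, had a median log2 difference of -0.12, and their groups overlapped (exact permutation p = 0.4). The 3 probe sets for 28S ribosomal RNA were higher by a median of 0.79 on the log2 scale (exact permutation p = 0.1) and those for 18S ribosomal RNA by 0.16 (exact permutation p = 0.6). Ratios of 3' to 5' signal, a measure of RNA integrity, were 0.926 to 0.955 for GAPDH in control arrays and 0.956 to 0.966 in BAHD1 siRNA arrays. For beta-actin they were 1.47 to 1.54 and 1.49 to 1.67.

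**Figure D3:**
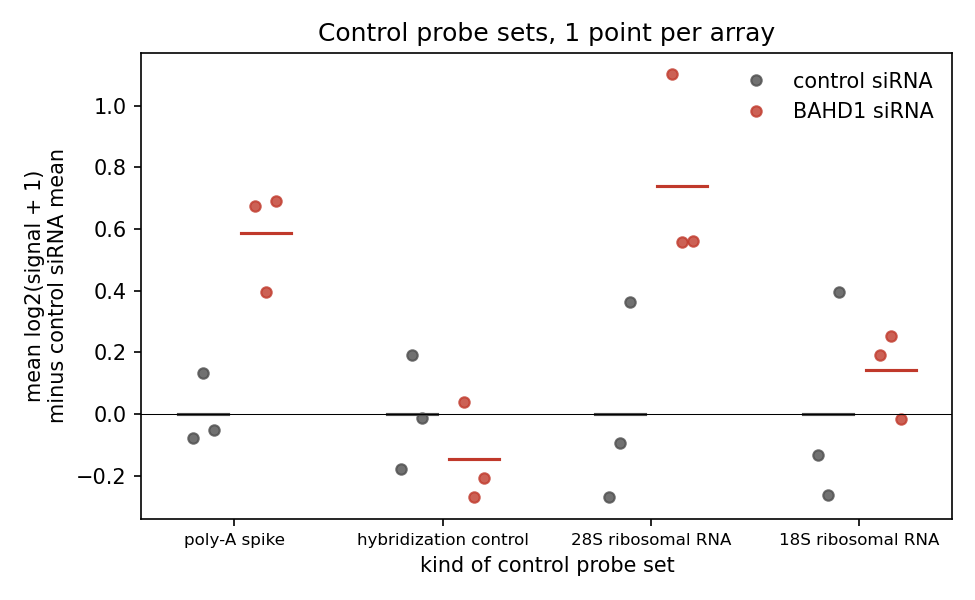
Mean log2(signal + 1) of each kind of control probe set per array, minus the mean of the 3 control siRNA arrays (vertical), with 1 point per array and a bar at each group mean. The poly-A spikes of the 3 BAHD1 siRNA arrays lay above those of all control arrays, whereas the hybridisation controls overlapped.

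Genes of the cell cycle and DNA replication were lower as a group. All 40 list members were measured, 30 were lower and 10 higher in BAHD1 siRNA cells, and the median log2 fold change was -0.12. The list passed camera's competitive test (adjusted p = 0.00189 over 21 lists, preset correlation 0.01) and fry's test (adjusted p = 0.00349). Its camera call was lost in the version that estimates the correlation between genes (adjusted p = 0.208). That estimate was -0.012, below the preset value, so a higher correlation between the list's genes does not account for the loss. CDC6, which loads the replicative helicase, changed by -0.61 ± 0.10, and AURKB, CDC25A and TYMS fell by 0.38, 0.28 and 0.25. The mitotic kinesin gene KIF11 rose by 0.37 ± 0.07, and the remaining 35 members did not pass. The camera call also ended when the signal-dependent shift of all genes was removed, an alternative added after the data were seen (adjusted p = 0.0999, median -0.10). It was kept after quantile normalisation of the arrays (camera adjusted p = 0.0328, median -0.11 relative to all genes). Adjusted over the list alone, 7 fell and 1 rose in the intensity-trend fit and none passed in the fit with one prior.

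Ribosomal protein genes were lower in 24 of 25 measured members, with a median log2 fold change of -0.11, and none passed singly in either fit, adjusted over all probe sets or over the list alone. The list passed camera (adjusted p = 0.00583) but not with an estimated correlation (adjusted p = 0.906) and not fry (adjusted p = 0.475). The estimated correlation between its genes was 0.78. The lowest member p-values belonged to RPL35, RPL18, RPL8 and RPL3, at -0.16, -0.18, -0.19 and -0.14, although the 2 other probe sets of RPL18 were higher (0.19 and 0.46) and RPL3 ran from -0.23 to -0.09 with one array left out. After quantile normalisation these 4 were at -0.05, -0.07, -0.05 and -0.01. The call was lost without control replicate 1, control replicate 2, BAHD1 siRNA replicate 2 or BAHD1 siRNA replicate 3 (adjusted p = 0.0617, 0.12, 0.0534 and 0.0759), and after quantile normalisation of the arrays (adjusted p = 0.986, median -0.03 relative to all genes). Of all probe sets in the brightest quartile, 42.1% were higher in BAHD1 siRNA cells, against 60.9% in the dimmest quartile, and after quantile normalisation these shares were 48.2% and 50.3%.

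Among extracellular matrix and adhesion genes, 5 of the 30 measured rose and 1 fell. NID1, which encodes the basement membrane protein nidogen, rose by 0.70 ± 0.08, the laminin gene LAMB1 by 0.46 ± 0.08, the metalloproteinase inhibitor gene TIMP3 by 0.50 ± 0.13, COL6A1 by 0.41 ± 0.09 and SPARC by 0.32 ± 0.08, whereas the collagen gene COL3A1 changed by -0.76 ± 0.16. The other 24 did not pass. Of the 4 probe sets kept for TIMP3 1 was called, and the others ran from -0.23 to 1.02, and 1 of the 5 for COL6A1 was called and the lowest was at -0.02. Adjusted over the list alone, the fit with one prior called 9 of the 30: NID1, TIMP3, LAMB1, COL6A1, COL5A1, SPARC and MMP2 were higher and COL3A1 and COL5A2 lower, and the intensity-trend fit called 7, with 5 higher. The list was not called by camera (adjusted p = 0.243, and 0.702 with an estimated correlation), and fry, which tests whether the genes move on balance one way, gave an adjusted p of 0.0271. With the stricter filter on dim probe sets camera did call it (adjusted p = 0.0236, median 0.13 relative to all genes).

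Of 17 imprinted genes measured, 4 rose and none fell. PHLDA2 rose by 0.62 ± 0.12 and the cell cycle inhibitor gene CDKN1C by 0.66 ± 0.15, and ZDBF2 and RB1 by 0.50 ± 0.11 and 0.45 ± 0.12, with the other probe set of RB1 at -0.12. The other 13 did not pass, and 8 members were lower. Adjusted over the list alone, PHLDA2 and CDKN1C passed in the fit with one prior (adjusted p = 0.0352 for each) and all 4 in the intensity-trend fit. The list as a whole was not called (camera adjusted p = 0.683, and 0.906 with an estimated correlation; fry adjusted p = 0.475).

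In the insulin-like growth factor list, IGFBP7 rose by 0.94 ± 0.12, and its other probe set by 0.94, and the other 17 of 18 measured genes did not pass. PAPPA2, HTRA1 and IGFBP5 had log2 fold changes of 0.72, 0.43 and 0.42, and the 5 probe sets kept for IGFBP5 ran from -0.32 to 1.16. In all, 15 of the 18 were higher. Adjusted over the list alone, IGFBP7 and PAPPA2 passed in the fit with one prior, and in the intensity-trend fit IGFBP7, PAPPA2, HTRA1 and IGFBP5, all higher, and STC2, at -0.22 (its other probe set 0.09). Camera did not call the list (adjusted p = 0.103, and 0.605 with an estimated correlation), and fry gave an adjusted p of 0.0121.

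Heterochromatin and repressor factors other than BAHD1 were mostly not past the threshold: 2 of 27 measured genes rose, the chromatin remodeller gene ATRX by 0.43 ± 0.09 and the DNA methyltransferase gene DNMT1 by 0.35 ± 0.09, and RCOR1 and UHRF1 had 0.34 and -0.20. Camera gave an adjusted p of 0.829, and adjusted over the list alone 3 genes passed in the intensity-trend fit, all higher. Interferon-stimulated genes included 1 rise among 23 measured, IFITM1 at 0.37 ± 0.09, while ISG20, IFITM2 and IRF7 had 0.63 (0.41 on the log2(signal + 16) scale), -0.29 and -0.48. Of the 23, 18 were higher, camera gave an adjusted p of 0.683 (0.906 with an estimated correlation) and fry 0.0271. With the signal-dependent shift removed, their median was 0.04 (camera adjusted p = 0.998). Without that step it was 0.11 relative to all genes, and 0.065 to 0.15 with one array left out. Of the unfolded protein and stress response genes, the chaperone genes HSP90B1 and CALR fell by 0.31 and 0.38, the cystine transporter gene SLC7A11 rose by 0.29 ± 0.07, PPP1R15A had -0.38, and 26 of 29 did not pass. The intensity-trend fit called 6 lower and 1 higher when adjusted over the list alone. This list had a camera adjusted p of 0.243 (0.618 with an estimated correlation) and a fry adjusted p of 0.045. Its median was -0.06 relative to all genes (-0.095 to -0.018 with one array left out) and -0.03 with the shift removed. Other probe sets of ATRX and SLC7A11 were as low as -0.03 and -0.09.

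Neural development genes moved in both directions. SEMA3C and SLIT2, which encode guidance cues, fell by 0.57 and 0.48, the neurofilament genes NEFM and NEFL rose by 0.58 ± 0.15 and 0.37 ± 0.10, EPHA4 and NLGN1 had 0.33 and -0.32, and 24 of 28 did not pass (camera adjusted p = 0.797). The other 3 probe sets of EPHA4 were lower, down to -0.31, and that of NLGN1 was at 0.07. SEMA3C and SLIT2 passed in the fit with one prior when adjusted over the list alone, as did 5 genes in the intensity-trend fit. Among developmental transcription factors NKX2-2, GATA3 and HOXB7 rose by 0.56 ± 0.13, 0.43 ± 0.10 and 0.37 ± 0.09, PAX2 had 0.65, and 37 of 40 did not pass (camera adjusted p = 0.591). In the Wnt and TGF-beta list ID3, an inhibitor of basic helix-loop-helix factors, fell by 0.54 and was the only one of 32 called (camera adjusted p = 0.411). ID3 also passed in the fit with one prior when adjusted over the list alone, and the intensity-trend fit then called PMEPA1, DKK3 and WNT5A as higher and ID3 as lower. PMEPA1, WNT5B and FST had 0.48, 0.68 and 0.52. Among p53 targets and apoptosis genes the survival gene MCL1 fell by 0.35, the ribonucleotide reductase gene RRM2B rose by 0.67 ± 0.13, BCL2L11 (another probe set 0.27) and PHLDA3 had -0.29 and 0.28, and 23 of 25 did not pass (camera adjusted p = 0.895). In the intensity-trend fit 3 p53 list genes were lower and 1 higher when adjusted over the list alone, and 3 transcription factors and 1 interferon-stimulated gene were higher; the fit with one prior called none of these 3 lists' genes.

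The remaining lists held few calls. MVK, of the cholesterol pathway, rose by 0.69 ± 0.16, 1 of 25 measured, with SREBF1 at 0.66, ELOVL6 at 0.28 and STARD4 at 0.38. Of 28 hypoxia and glycolysis genes, ADM fell by 0.47 and the hexokinase gene HK2 rose by 0.50 ± 0.13, while EGLN3 and P4HA1 had 0.46 (another probe set -0.18; 0.27 on the log2(signal + 16) scale) and -0.26. Of 29 oxidative phosphorylation genes, NDUFA9 and SDHD rose by 0.33 ± 0.08 and 0.26 ± 0.07, and UQCRC1 and SDHC had -0.24 and -0.27. Of 15 RNA interference genes, SND1 fell by 0.46, and TNRC6C, MOV10 and DROSHA had 0.50, -0.24 and 0.31. None of 22 immediate early genes was called (NR4A1 -0.70, SPRY2 0.26, JUN -0.33, SPRY1 0.21). Camera gave these 5 lists adjusted p-values of 0.829, 0.797, 0.244, 0.82 and 0.893, and called the oxidative phosphorylation list lower without control replicate 3 (adjusted p = 0.0199). Each count rests on the brightest probe set of a gene. The lowest probe sets of MVK, ELOVL6 and SPRY1 were at -0.08, -0.25 and -0.01. Another probe set was called for ELOVL6 (higher), MOV10 and JUN (lower) and SDHC (higher, against the sign of its brightest). Adjusted over the list alone, the fit with one prior called none in these 5 lists, and the intensity-trend fit called 4 in the cholesterol list, 2 in the hypoxia list, 4 in the oxidative phosphorylation list, 5 in the RNA interference list and none of the immediate early genes.

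Markers of other cell types, kidney epithelium and germline showed 1 call among the few genes measured. Measured were 8 of 22 fibroblast and endothelial, 4 of 24 leukocyte, 9 of 23 kidney epithelial and 4 of 40 germline genes. Genes above the filter level in fewer than 3 arrays were not tested, so the lack of calls does not cover them. COL3A1 was the call among 8 measured fibroblast and endothelial markers, in which EGFL7, COL1A1 and TAGLN had 0.62, 0.37 (another probe set -0.37) and 1.11; adjusted over the list alone, COL3A1 (lower) and EGFL7 (higher) passed in both fits. TAGLN was at 0.15 without control replicate 3, and its other probe set was at -0.74. None was called among 4 leukocyte markers (LCP1 -0.77, CD8A 0.57, HLA-DPA1 -0.12, CD79A 0.08), 9 kidney epithelial markers (WT1 0.21, EPCAM 0.37, AQP2 0.65, KRT8 0.09) or 4 germline and cancer-testis genes (TEX15 0.45, MAGEA1 0.19, MAGEA12 0.05, MAGEA6 -0.03). With one array left out, TEX15 ranged from 0.20 (without control replicate 1) to 0.68 (without control replicate 2), and its other probe set was at -0.02. Without BAHD1 siRNA replicate 3, LCP1 was at -0.50 and WT1 at 0.10, EPCAM was at 0.20 without control replicate 2, and CD8A, AQP2, KRT8, MAGEA1 and MAGEA6 crossed 0. HLA-DPA1 ran from -0.20 to -0.012 with one array left out, CD79A from 0.0040 to 0.21 and MAGEA12 from 0.013 to 0.073. On the log2(signal + 16) scale TAGLN, LCP1, CD8A, AQP2 and MAGEA1 were at 0.47, -0.48, 0.30, 0.33 and 0.12, and after quantile normalisation KRT8, MAGEA1, MAGEA6 and CD79A were at 0.0084, 0.07, -0.0017 and -0.02. With array medians centred MAGEA12 and MAGEA6 were at 0.02 and -0.05. Camera adjusted p-values for these 4 lists were 0.826, 0.797, 0.797 and 0.797. Across all 21 lists, camera called 2 with the preset correlation and 0 with an estimated one, where 1 list had an unadjusted p under 0.05, and fry called 5. For p53 targets, RNA interference and neural genes the list median and mean were above 0 (medians 0.04, 0.04 and 0.007) while camera's direction was lower, and for the cholesterol and hypoxia lists the median was below 0 (-0.007 and -0.02) and the mean above it (0.02 and 0.01).

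**Figure D4:**
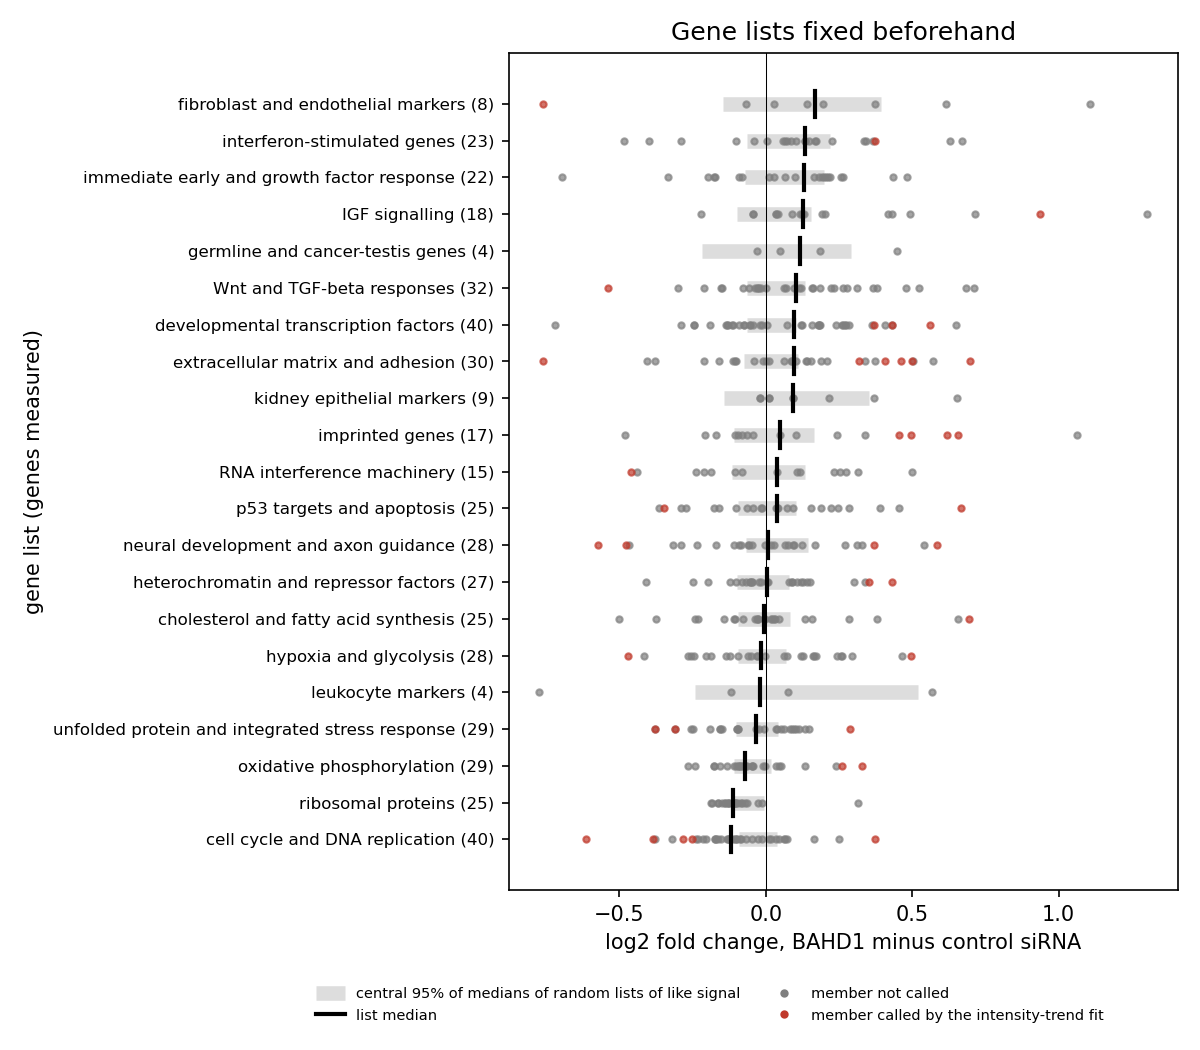
Log2 fold change of BAHD1 siRNA over control siRNA for each measured gene (points, red where called by the intensity-trend fit) in 21 gene lists fixed before the data were examined, with the list median as a black bar. Grey bars span the central 95% of medians of 10000 random lists of genes of like mean signal; the cell cycle list, at -0.12, lies below its range of -0.09 to 0.04.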

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

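The tests in this part were chosen after the values of the control probe sets had been seen.

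The probe sets for bacterial poly-A RNAs, which no comparison of genes used, stood 1.49 times higher (median over 24 probe sets) in the BAHD1 siRNA arrays than in the controls. Array scaling is argued against, because the hybridisation controls were scaled by the same factor and had a median log2 difference of -0.12, against 0.58 for the poly-A spikes. What stays open is a labelling session or spike dilution that differed between the groups, or less poly-A RNA per amount of total RNA in the knockdown cells. The lowest BAHD1 siRNA array lay 0.26 above the highest control array on the log2 scale, which is what either would give, and since each group is on one side they cannot be told apart. The 28S ribosomal RNA probe sets, at 0.79 higher, may go with a lower poly-A share but are only 3, with groups that did not overlap in 2 of them, and those for 18S ribosomal RNA differed by 0.16 with overlap. The 28S probe sets were also dim, with a mean log2 signal of 4.78 ± 0.33 (SD, n = 3) in control arrays and 5.52 ± 0.31 in BAHD1 siRNA arrays. That control level is within the range of the dimmest quartile of probe sets kept, of which 60.9% were higher in BAHD1 siRNA arrays. If labelling did differ by group, any gene difference reported above could include it.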

How the results depend on the processing

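The removal of the signal-dependent shift, the alternatives of the intensity-trend fit and the counts at an unadjusted p were added after seeing the data. The fit with one prior called 0 probe sets under a replicate block, no filter, quantile normalisation, centred medians, array weights, log2(value + 16) and a threshold of 0.1; it called 1147 with the stricter filter and 1221 as the intensity-trend fit, and 0 to 4 with one array left out. At 2-fold it called 0, 2 with the stricter filter, 42 in the intensity-trend fit, 196 at an unadjusted p under 0.05, and 0 to 4 with one array left out. The count at an unadjusted p under 0.05 ran from 3421 to 5743 over the 14 alternatives. These did not all test the same number of probe sets: 13876 with the stricter filter, 27458 in the main set and more without the filter. The count by chance differs with that number, so the range does not measure stability. The intensity-trend fit called 398 without the filter, 177 to 1174 with one array left out, and 1204 to 1629 otherwise. In the fit with one prior the replicate block changed no call of a list or named gene, and the block gave 1629 calls in the intensity-trend fit against 1221; deviations of same-numbered samples correlated at 0.010, 0.010 and 0.024, so the numbers were not taken as a pairing. BAHD1 (-0.51 to -0.30) and the IGF2 probe set (0.59 to 1.20) kept direction, and neither passed the adjusted threshold under any alternative that kept them (adjusted p 0.194 to 0.55 and 0.115 to 0.517). Both had an unadjusted p under 0.05 in the fit with one prior.

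Of the gene lists, 2 were called; 0 were with an estimated correlation, 1 with probe sets averaged per gene, 1 after quantile normalisation, 0 after removing the signal-dependent shift, 3 with the stricter filter, and 1 to 3 with one array left out. The lists that gained a call were extracellular matrix and adhesion with the stricter filter (median 0.13, adjusted p = 0.0236) and oxidative phosphorylation without control replicate 3 (-0.13, adjusted p = 0.0199). Medians below are log2, relative to all genes, except those without the signal-dependent shift. These are plain medians of the shift-removed fold changes, so a change of sign near 0 there is not a strict comparison. The cell cycle list (-0.14) lost its call with an estimated correlation (-0.14) and without the signal-dependent shift (-0.10). It kept the call after quantile normalisation (-0.11) and with one array left out (-0.15 to -0.13). The ribosomal list (-0.14) lost it with an estimated correlation (-0.14), averaged probe sets (-0.12), without the signal-dependent shift (-0.040) and after quantile normalisation (-0.030), and lay at -0.20 to -0.09 with one array left out. Some lists that were never called changed the sign of their median. With averaged probe sets these were heterochromatin factors (0.0054) and p53 targets (-0.042); without probe sets of shared sequence, p53 targets (-0.050) and hypoxia (0.091); without the signal-dependent shift, heterochromatin factors (0.011), hypoxia (0.043), fibroblast and endothelial markers (0.14 to -0.053) and kidney markers (-0.0056). Without the filter they were imprinted genes (-0.032), p53 targets (-0.013), RNA interference (-0.012), leukocyte markers (-0.045 to 0.27) and kidney markers (-0.021); with the stricter filter, heterochromatin factors (0.014), neural genes (0.0054), immediate early genes (-0.0034), RNA interference (-0.013) and kidney markers (-0.0098). After quantile normalisation they were heterochromatin factors (0.0044), hypoxia (0.049), kidney markers (-0.0087) and the gene CD79A (-0.021), and with array weights RNA interference (-0.026). With one array left out, medians crossed 0 for RNA interference (-0.099 to 0.040), cholesterol (-0.088 to 0.020), heterochromatin factors (-0.055 to 0.038), hypoxia (-0.068 to 0.014), imprinted genes (-0.017 to 0.081), kidney markers (-0.031 to 0.22), neural genes (-0.060 to 0.031) and p53 targets (-0.011 to 0.030), and values for AQP2 (-0.072 to 1.33), CD8A (-0.0074 to 0.91), KRT8 (-0.061 to 0.25), MAGEA1 (-0.018 to 0.39) and MAGEA6 (-0.068 to 0.0010). Medians of fibroblast and endothelial markers (0.041 to 0.18) and leukocyte markers (-0.12 to -0.0070) kept their sign with one array left out but varied in size. The causes were not tested. Dim probe sets had a median residual SD of 0.37 on the log2 scale in the lowest quartile of signal, against 0.094 in the highest, which limits what their changes can show.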

Other observations

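The choice of genes with several called probe sets (SAR1A, SAR1B and MIA3 among them), the tests of the variance prior, the removal of the signal-dependent shift and the splits for the counts of the fit with one prior came after the results were seen; the matched random lists, families and neighbours were set beforehand. In the intensity-trend fit, 106 genes had at least 2 called probe sets, of which 71 fell on each, 32 rose on each and 3 went both ways. Falls with the largest least change were PON2 (-0.82 and -0.81), TNKS2 (-0.80 on both called), ZMYND11 (3 of 3 probe sets, -0.88 to -0.77), a chromatin reader gene, and SESN3 (-0.81 and -0.62). Rises were led by IGFBP7 (0.94 on both), LMF1, NID1 (0.70 and 0.74) and FAR1, a peroxisomal reductase gene (0.67 and 0.70). EMP2 and SAT1, the latter a polyamine acetyltransferase gene, rose on 3 of 3 probe sets (0.57 to 0.96 and 0.46 to 0.58). The circadian gene CLOCK fell on 3 of 3 (-0.66 to -0.47).

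SAR1A, a GTPase of vesicle budding from the endoplasmic reticulum, fell on 3 of 3 probe sets (-0.75 to -0.49), and its paralogue SAR1B rose on 2 of 5 (0.56 and 0.83), while another of its probe sets was at -0.86 and did not pass. MIA3 fell on 3 of 3 (-0.86 to -0.48). The 3 genes with called probe sets of opposite direction were TRPC1 (-0.65 and 0.43), RRP7A (-0.37 and 0.60) and CDYL (-0.65 and 0.35), a corepressor of the heterochromatin list. Which transcripts these probe sets read was not examined.

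The fit with one prior called none and the intensity-trend fit 1221. The noise of dim probe sets is a candidate explanation: the model with one prior, fitted to the 13876 brighter probe sets alone, called 1147. Of the 1221, 71.8% were also called by that model, so these calls did not need a trend term. Whether the trend makes false calls cannot be decided from this overlap. Both fits used the same arrays, and for bright probe sets both took their prior from probe sets of like signal, so a large overlap was likely either way. The overlap also reaches bright probe sets only: of the 24 genes with the largest rises and falls, PCDH10 and UBL3 alone were among the 13876. Whether the changes come from BAHD1 depletion or from another difference between the groups, such as labelling, stays open.

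Bright genes were lower and dim genes higher in BAHD1 siRNA arrays by small amounts that depended on signal. The ribosomal list's median lay at percentile 2.93 among 10000 random lists of like signal, within the central 95%, which is consistent with the signal-dependent shift. The cell cycle list's lay at percentile 0.19, which argues against that shift as its whole cause. With the shift removed its median was -0.10 and camera gave an adjusted p of 0.0999, against 0.00189 before. After quantile normalisation of the arrays camera gave it an adjusted p of 0.0328. A labelling difference between the groups and an effect of the knockdown both stay open for this list.

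As BAHD1 acts on heterochromatin, a regional effect would make neighbours change together. The rank correlation of signal-adjusted fold changes between 12484 adjacent gene pairs was 0.013, under the 95th percentile of 1000 shuffled orders (0.016; one-sided permutation p = 0.0989), which neither shows nor excludes such an effect. Of 52 families of at least 20 genes that share a symbol stem, 0 passed camera (smallest adjusted p = 0.0962, 7 at an unadjusted p under 0.05) and 2 passed fry (DDX helicases, adjusted p = 0.0141, and SLC transporters, 0.0084).

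The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The intensity-trend fit called 1221 in the real split and at most 1 in the others (1 split as large), and 4843 probe sets had an unadjusted p under 0.05 against at most 1652 (1 split as large). The fit with one prior called 0 in the real split and at most 1 in others, at any fold and at 2-fold (10 splits as large for each). Camera with the preset correlation called 2 lists in the real split and at most 2 in others (3 splits as large, the real one included), and 1 list in further splits. Its list calls thus also arise in other groupings of these arrays.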
